A study of Homo sapiens with 9 samples.

How the data were processed

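The series is a pooled CRISPR knockout screen in A549, an established human lung adenocarcinoma cell line, engineered to express Cas9. Cells were transduced with a guide library aimed at epigenetic regulators and the targets of approved drugs, selected with puromycin, and then either sampled at once, kept in culture, or implanted in NOD/SCID mice, which lack functional T and B cells. The labels give 9 samples: 2 day 0 samples, 2 samples grown in vitro and 5 xenograft tumours harvested at day 14. The length of the in vitro culture is not given in the sources used here. Each sample is genomic DNA from which the integrated guide sequences were amplified and sequenced, per the labels' protocols. Nothing in the labels says whether replicates of a group came from separate cultures.

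The measurements are 2 gene summary tables of the authors' own comparisons, 1 for the in vitro arm and 1 for the xenografts, and no column holds per-sample values (0 columns). The submitters' processing notes name MAGeCK, a program that ranks genes by the enrichment or depletion of their guides, and the genome build hg38, with no MAGeCK version. The labels tie the day 0 and the in vitro samples to the in vitro table, which was read as in vitro growth against day 0. The labels tie the 5 tumours to the xenograft table. The baseline of the xenograft table is not given in the sources used here, nor are the read normalization, the guide filter and the rule that combined guides into a gene value. The log2 fold change of each gene was deposited by the authors as a single value, the same in the depletion and enrichment columns. One-sided p-values and false discovery rates (FDR) for depletion and for enrichment were deposited by the authors for each gene. The rank aggregation score of each gene, per the file headers, was not used. The tables further give the number of guides per gene, its rank in each direction and the number of guides past the authors' ranking threshold in that direction, called supporting guides here. The deposited FDR differed from a Benjamini-Hochberg adjustment of the deposited p-values by at most 2.9e-05.

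The deposited guide list holds 11129 guides, fewer than the labels state for the whole pool, of which 10750 have 19 bases and 379 have 20 bases. Each table holds 1332 entries. Of these, 1048 are genes and 284 are control entries, whose names begin with AAVS (100), CTRL (100), LacZ (60) or luciferase (24). The guide numbers per entry equal those of the library list in 1332 of 1332 entries. Of the genes, 966 have 10 guides and 23 have fewer than 8, with a range of 1 to 65. Symbols were matched to the RefSeq annotation of GRCh38.p14, where 1024 matched by symbol, 23 by an older symbol and 1 not at all. Gene coordinates are from that annotation. Guide positions within exons were not determined, since no genome sequence was used here.

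Among xenograft values, 293 entries share a log2 fold change of exactly -0.27 in the authors' deposited table, namely all 284 control entries and 9 genes. These are the 293 entries made of 20-base guides, and 0 entries made of 19-base guides hold that value. The shared value was treated as a placeholder. This departs from the design fixed before the data were examined, which had foreseen all genes. Analyses of the xenograft table, and of both tables together, therefore cover the 1039 genes with 19-base guides, and the 9 genes were kept in as an added alternative.

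Depth per sample is unknown, since the tables hold no read counts, so no counting interval is given. The tests of single genes are the authors' own, at an FDR below 0.05 per direction. A replicate was never left out and no between-replicate spread was computed, because the tables hold no value per replicate. Overlaps of called genes were tested with a two-sided Fisher exact test over 1039 genes. Pearson and Spearman correlations across genes used 100000 permutations. The difference between the arms was taken as the xenograft minus the in vitro log2 fold change, minus its median over genes, divided by 1.4826 times its median absolute deviation, and genes beyond 3 in either direction were counted. This scaled difference uses the spread between genes and is not a test against replicate error. It was to be read as a difference in vivo only if the ribosome, proteasome and DNA replication lists were lower in both tables. The ribosome list could not be tested in the xenograft table, where 1 of its genes has a value.

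The 35 gene lists were fixed before the data were examined. A list with at least 4 measured genes was tested in each table by setting its median against 10000 random lists of the same size, as a two-sided permutation test across genes, with Benjamini-Hochberg adjustment over the 59 tests of both tables and over 29 tests for the difference. Genes are not independent replicates, so these p-values describe the lists within these tables. Named genes followed a rule fixed before the data were examined: MEN1, the 12 best-ranked genes per table and direction among those past the threshold (the 5 best-ranked where fewer than 5 passed), the 10 lowest and 10 highest scaled differences, up to 4 members per list with the smallest p, and the genes of any count of 5 or fewer. Control classes were compared with AAVS entries by 20000 permutations, and intervals are 95% bootstrap intervals over genes or guides.

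The scripts were tested on simulated data. With known shifts added to 1039 genes, the scaled difference found 3.1% of genes shifted by 2 log2 units, 15.9% of those shifted by 4 and 68.7% of those shifted by 6, and 0% of unshifted genes. These were 64, 69 and 67 genes shifted up or down at the same time, which enters the spread used for scaling. Simulated values had no lower limit, whereas xenograft values reached no lower than -3.84, so rates for downward shifts may not carry over. The list test found 42.9% of lists shifted by 0.5 in vitro and 28.6% of lists shifted by 1 in the xenograft table, and 0% of unshifted lists. Each of these list rates rests on 7 shifted or 20 unshifted lists. Alternatives changed the FDR threshold, the guide minimum, an effect size filter, joint adjustment of both directions, a minimum of supporting guides, the scaling of the difference, and the statistic, chromosome centring and GC adjustment of the lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.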

Results

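Guide abundance was compared between Cas9-expressing A549 lung adenocarcinoma cells before growth (day 0, 2 samples), after growth in culture (2 samples) and in xenograft tumours of NOD/SCID mice at day 14 (5 samples). A negative log2 fold change means that guides against a gene became rarer, and a positive one that they became more frequent. The series title names MEN1 as a regulator of tumour and microenvironment interactions, and the comparisons ask which gene losses slow or favour growth in culture and in the mouse. All gene values are the authors' own, combined over replicates, so none carries a replicate error and the sequencing depth behind them is unknown.

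Growth in vitro was compared with day 0 first. Guides against 97 of 1048 genes were depleted at an FDR below 0.05, with a median log2 fold change of -1.91 in the authors' deposited table. The best-ranked genes included ribosomal protein genes, whose list is tested below. The other best-ranked genes are named singly, and they were not tested as a group. In the authors' deposited table the ribosomal protein genes RPL4, RPL5, RPL19 and RPL3 had log2 fold changes of -3.80, -3.43, -3.0 and -2.85. The authors' deposited table gave -2.88 for RRM1, the large subunit of ribonucleotide reductase, -2.17 for CHEK1, a DNA damage checkpoint kinase, and -2.48 for TUBG1, the gamma-tubulin of the centrosome. It listed, in the authors' deposited table, -2.60 for PRMT5, an arginine methyltransferase, -1.72 for OGT, which attaches N-acetylglucosamine to proteins, -2.44 for PHB (now PHB1), a prohibitin, and -1.42 for FTSJ3, an RNA methyltransferase of ribosome assembly. Each of these genes had an FDR of 0.00011, and apart from FTSJ3 10 of 10 guides supported depletion in the authors' deposited table. FTSJ3 had 22 supporting guides. At an unadjusted p below 0.05 the count was 153 genes.

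Guides against 9 genes were enriched in vitro, with log2 fold changes from 0.55 to 1.15 in the authors' deposited table. The same threshold was passed by 4 control entries, which makes 13 enriched entries with them counted. KDM5C, an H3K4 demethylase encoded on the X chromosome, had the highest value, 1.15 with an FDR of 0.0016 in the authors' deposited table. The Y-linked chromodomain genes CDY1 and CDY2A had the same FDR with 0.97 and 0.86 in the authors' deposited table. The other Y-linked genes measured, KDM5D, UTY and TBL1Y, had 0.80, 0.77 and 0.67 there and did not pass. Since these values lie close together, the calls of CDY1 and CDY2A cannot be read as particular to either gene. The authors' deposited table further gave 0.98 for EPHA2, a receptor tyrosine kinase, 0.89 for USP28, a deubiquitinase, 0.69 for PRKAA2, a catalytic subunit of AMPK, 0.67 for LEPR, the leptin receptor, 0.65 for YTHDF3, a reader of N6-methyladenosine in RNA, and 0.55 for NSUN6, an RNA cytosine methyltransferase. Guides without a target in the human genome (CTRL, LacZ and luciferase, 182 single-guide entries) had a median of 1.06 in the authors' deposited table, and 1 of the 9 enriched genes lay above it. The count of enriched genes was 23 when both directions were adjusted together and 113 at an unadjusted p below 0.05.

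**Figure D1:**
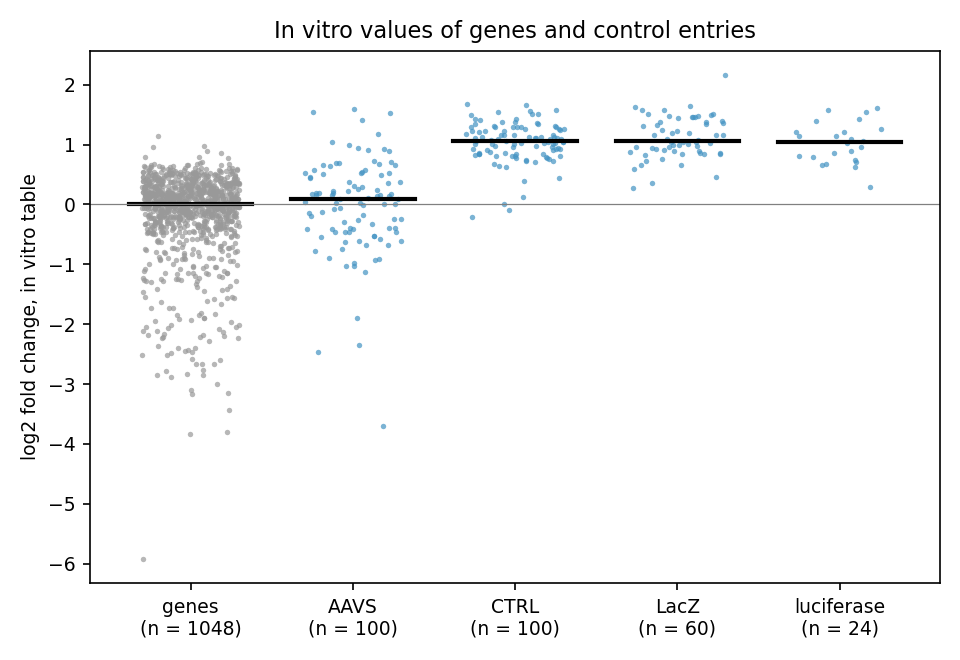
Log2 fold change in the authors' deposited in vitro table (y axis) for genes and for the control entries named AAVS, CTRL, LacZ and luciferase (x axis). Each point is 1 entry and each bar is the median of its class: the genes' median was 0.0067, that of AAVS entries 0.089, and those of CTRL, LacZ and luciferase entries 1.06, 1.06 and 1.04.

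Gene lists fixed beforehand were then set against random lists of equal size. The 7 measured ribosomal protein genes were all depleted in vitro (7 adjusted over the list alone), with a median log2 fold change of -3.0 and an adjusted permutation p of 0.0017. Of these only RPL3 has 19-base guides, while the others have 20-base guides like the control entries. Among the 1048 genes from which random lists were drawn, 1039 have 19-base guides. Without the genes of 20-base guides 88 genes were depleted in vitro, against 97 with them. Among 11 DNA replication and topoisomerase genes 7 were depleted (7 adjusted over the list alone), with a median of -2.37 and an adjusted permutation p of 0.0017. They included POLE and POLE2 of DNA polymerase epsilon at -3.10 and -2.58 in the authors' deposited table. Of 13 tubulin and mitotic kinase genes 8 were depleted (10 adjusted over the list alone), with a median of -1.73 and an adjusted permutation p of 0.0017. Among them the authors' deposited table had AURKB at -3.83, PLK1 at -2.24 and TUBD1 at -2.09. Of 8 proteasome genes 5 were depleted (5 adjusted over the list alone), with a median of -1.58 and an adjusted permutation p of 0.0017. The constitutive subunit genes PSMB1, PSMD2, PSMB5 and PSMD1 had -3.15, -2.44, -2.28 and -1.56, and the immunoproteasome subunit gene PSMB8 had 0.20, in the authors' deposited table.

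The family of menin, KMT2A and related COMPASS complexes, which methylate histone H3 at lysine 4, was lower in vitro. Of its 16 measured genes 8 were depleted (11 adjusted over the list alone), with a median of -1.18 and an adjusted permutation p of 0.0017. In the authors' deposited table WDR82 had -2.67, WDR5 -2.39 and HCFC1 -2.23, while PAXIP1 had 0.61 and passed in neither direction. The SAGA, ATAC and TFIID list, coactivator complexes that include histone acetyltransferases, had 3 of 22 genes depleted (6 adjusted over the list alone) and a median of -0.32, with an adjusted permutation p of 0.039. Those 3 were TRRAP at -2.83, TADA2A at -1.14 and ATXN7L3 at -0.80 in the authors' deposited table. The SAGA, ATAC and TFIID result did not pass when the mean of the list was used (adjusted permutation p = 0.30), when genes were ranked by p (0.10) or when chromosome medians were removed (0.17).

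The other lists tested in vitro did not pass. Adjusted permutation p was 0.064 for 14 nucleotide synthesis genes (median -0.40), 0.093 for 7 cholesterol and isoprenoid synthesis genes (-0.72), 0.15 for 10 chromatin remodeller genes (-0.39), 0.20 for 5 DOT1L and PAF1 complex genes (-0.57) and 0.21 for 8 cell cycle, checkpoint and tumour suppressor genes (-0.37). Single members past the threshold were GGPS1 at -2.12, RUVBL1 at -2.47, RUVBL2 at -2.20 and PAF1 at -1.28 in the authors' deposited table. Medians of the remaining chromatin lists were -0.29 for 8 arginine methyltransferase genes (adjusted permutation p = 0.29), -0.16 for 19 histone deacetylase and sirtuin genes (0.33), -0.15 for 5 PRC2 genes (0.70), -0.13 for 7 NuRD and CoREST genes (0.70), -0.08 for 10 H3K9 and H4K20 methylation genes (0.74), -0.07 for 26 MYST, NuA4 and p300/CBP genes (0.57), -0.012 for 9 PRC1 genes (0.95), -0.0052 for 22 histone lysine demethylase genes (0.95), 0.024 for 6 DNA methylation genes (0.95) and 0.14 for 19 H3K36 and other SET-domain genes (0.50). Among drug targets the medians were -0.22 for 5 vacuolar and P-type ATPase genes (adjusted permutation p = 0.54), 0.027 for 20 other receptor tyrosine kinase genes (0.95), 0.032 for 101 neurotransmitter receptor and ion channel genes (0.76), 0.058 for 9 redox and drug-response genes (0.95), 0.12 for 27 angiogenesis, adhesion and matrix genes (0.52), 0.13 for 17 carbonic anhydrase, phosphodiesterase and cyclooxygenase genes (0.54), 0.14 for 20 nuclear hormone receptor genes (0.50), 0.16 for 29 immune and cytokine genes (0.24) and 0.16 for 11 EGFR, RAS and MAPK genes (0.54). Median and mean had opposite signs for 4 lists in vitro, those of DNA methylation, EGFR signalling, other receptor tyrosine kinases and angiogenesis. Too few genes were measured to test SWI/SNF (2 genes, median -1.64), BET and other bromodomain readers (3, -0.35), mTOR signalling (2, -1.23) and the respiratory chain (1, -0.35). No gene of the histone chaperone list was measured (0 of 19).

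The xenograft table shows which guides changed in tumours at day 14, against a baseline that is not given in the sources used here. Guides against 5 genes were depleted at an FDR below 0.05, each with an FDR of 0.035 in the authors' deposited table. RPL3, a ribosomal protein gene on chromosome 22 (39312882 to 39319623, GRCh38), had a log2 fold change of -3.84 with 9 of 10 supporting guides in the authors' deposited table. OGT, on the X chromosome (71533104 to 71575892), had -3.27 with 9 supporting guides in the authors' deposited table. YTHDC1, the nuclear reader of N6-methyladenosine on chromosome 4 (68310387 to 68350090), had -3.12 with 9 supporting guides in the authors' deposited table. PRMT5 on chromosome 14 (22920529 to 22929376) had -3.10 with 9, and POLE2 on the same chromosome (49643555 to 49688214) had -3.05 with 10 supporting guides, in the authors' deposited table. At an unadjusted p below 0.05 the count was 87 genes, and 0 genes passed when both directions were adjusted together.

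No gene passed the threshold for enrichment in xenografts (0 genes by the authors' MAGeCK test, and 86 at an unadjusted p below 0.05). MEN1, which encodes menin, a scaffold of KMT2A complexes, ranked first with a log2 fold change of 4.58, p = 7.1e-05 and an FDR of 0.094 in the authors' deposited table. The next ranks, which did not pass either, were YTHDF3 at 2.05, UBE2A, a ubiquitin-conjugating enzyme that modifies PCNA and histone H2B, at 4.20, TFPI, an inhibitor of blood clotting, at 3.29, and TNFSF13B, the cytokine BAFF, at 1.60, each with an FDR of 0.14 in the authors' deposited table.

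Log2 fold changes spread further in the xenograft table than in vitro. Over genes the median was -0.77 with a scaled median absolute deviation of 1.54 in the xenograft table, against 0.0067 and 0.41 in vitro. Among 101 neurotransmitter receptor and ion channel genes, a reference that a lung epithelial line is not thought to need, the spread was 4.85 times that in vitro (95% bootstrap interval 3.52 to 6.57). Of this reference 1 gene, HTR1A, was itself called depleted in vitro, at -1.20 with an FDR of 0.036 in the authors' deposited table.

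Proteasome genes were lower in xenografts as a list, with a median of -2.92 over 8 genes (adjusted permutation p = 0.0017), although 0 passed singly and 2 passed adjusted over the list alone. In the authors' deposited table PSMD2 had -3.50 and PSMB8 -3.01. Tubulin and mitotic kinase genes had a median of -2.50 over 13 genes (adjusted permutation p = 0.0017), with 0 depleted and 3 adjusted over the list alone. The authors' deposited table listed PLK1 at -3.75 and TUBG1 at -2.50. The 11 DNA replication and topoisomerase genes had a median of -2.30 (adjusted permutation p = 0.018), with 1 depleted and 5 adjusted over the list alone, and did not pass by their mean (adjusted permutation p = 0.11). RRM1, POLE and RRM2 stood at -3.34, -3.27 and -3.11 in the authors' deposited table.

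The list of H3K9 and H4K20 methylation was higher in xenografts than random lists. Its 10 measured genes had a median of 0.88 against -0.78 for random lists (adjusted permutation p = 0.033), with 0 enriched and 1 adjusted over the list alone. EHMT1 and EHMT2, the paired H3K9 methyltransferases GLP and G9a, had 2.89 and 2.54, while PRDM2 had -0.45 and the H4K20 methyltransferase SETD8 (now KMT5A) had -1.82, in the authors' deposited table. This list did not pass when genes were ranked by p (adjusted permutation p = 0.10), when chromosome medians were removed (0.12) or after adjustment for guide GC content (0.088). Its median stayed above that of random lists by 1.27 without chromosome medians and 1.45 after GC adjustment, against 1.66 in the main setting. The lost call therefore does not show that chromosome or GC content accounts for the list.

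The menin, KMT2A and COMPASS list had a median of -1.54 in xenografts over 16 genes and did not pass (adjusted permutation p = 0.24). Its members went apart, with WDR5 at -3.16, PAXIP1 at -3.14, WDR82 at -1.57 and HCFC1 at -0.74 against MEN1 at 4.58 in the authors' deposited table. Adjusted permutation p was 0.072 for 29 immune and cytokine genes (median 0.14, mean -0.08), 0.094 for 8 cell cycle genes (-2.09), 0.20 for 6 DNA methylation genes (-1.99), 0.20 for 9 redox and drug-response genes (0.49), 0.21 for 22 SAGA, ATAC and TFIID genes (-1.48), 0.26 for 14 nucleotide synthesis genes (-1.55), 0.28 for 19 H3K36 and other SET-domain genes (-0.09) and 0.50 for 8 arginine methyltransferase genes (-1.50). Cyclin D1 partner kinase genes CDK4 and CDK6 had -3.12 and -2.17, and neither passed, in the authors' deposited table. The remaining medians were -1.35 for 10 remodeller genes (adjusted permutation p = 0.54), -1.17 for 26 MYST, NuA4 and p300/CBP genes (0.54), -1.13 for 19 histone deacetylase and sirtuin genes (0.72), -1.04 for 22 histone lysine demethylase genes (0.74), -0.30 for 5 PRC2 genes (0.74), -0.97 for 7 NuRD and CoREST genes (0.95), -0.83 for 9 PRC1 genes (0.95) and -0.85 for 5 DOT1L and PAF1 complex genes (0.95). Among drug targets they were -1.07 for 27 angiogenesis, adhesion and matrix genes (adjusted permutation p = 0.74), -0.46 for 17 carbonic anhydrase, phosphodiesterase and cyclooxygenase genes (0.73), -1.15 for 5 ATPase genes (0.92), -0.87 for 20 other receptor tyrosine kinase genes (0.95), -0.71 for 11 EGFR, RAS and MAPK genes (0.95), -0.83 for 101 neurotransmitter receptor and ion channel genes (0.95), -0.74 for 20 nuclear hormone receptor genes (0.95) and -0.72 for 7 cholesterol and isoprenoid synthesis genes (0.95). Untested lists had medians of -2.39 for SWI/SNF (2 genes), -1.58 for BET and other bromodomain readers (3), -0.42 for mTOR signalling (2) and -0.27 for the respiratory chain (1).

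Both arms were then set side by side over the 1039 genes with a value in each. Of 88 genes depleted in vitro and 5 depleted in xenografts, 4 were shared (RPL3, OGT, PRMT5 and POLE2), where independent lists would share 0.42 (Fisher exact p = 0.00023). YTHDC1, the fifth, had an in vitro log2 fold change of -0.90 and an FDR of 0.075 in the authors' deposited table. Of the 88 genes, 71 lay below the xenograft median, 34 had a one-sided depletion p below 0.05 there, and 5 lay above 0. These 5 were ITGAV, MEN1, TGS1, SLC52A2 and BRCA2, with xenograft log2 fold changes of 0.53, 4.58, 0.38, 0.51 and 0.98 in the authors' deposited table. Of the 9 genes enriched in vitro, 8 lay above the xenograft median. Their overlap with xenograft enrichment could not be tested, since 0 genes passed there. Across genes, which are not independent replicates, log2 fold changes correlated with Pearson r = 0.41 and Spearman rho = 0.44 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Their covariance was 0.40, and r was 0.41 without the 2 genes farthest from the in vitro median. Part of the overlap and correlation may come from day 0 libraries if both comparisons used them, which could not be simulated without per-sample counts.

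MEN1, on chromosome 11 from 64803516 to 64811294 (GRCh38), lay apart from other genes between the arms. In vitro it was depleted, with a log2 fold change of -1.12, an FDR of 0.0096 and 9 of 10 supporting guides in the authors' deposited table. In xenografts its log2 fold change was 4.58, and 7 of its 10 guides supported enrichment while 3 supported depletion in the authors' deposited table. The difference was 5.70 log2 units, a scaled difference of 4.53 and the highest of 1039 genes. All differences depend on the unstated xenograft baseline: if it was the in vitro arm, the in vitro value entered them 2 times. UBE2A, on the X chromosome from 119574563 to 119584423, had 0.15 in vitro and 4.20 in xenografts in the authors' deposited table, a scaled difference of 3.35. No other gene lay beyond 3. The count of 0 genes beyond -3 says little, because xenograft values reached no lower than -3.84 and in vitro values no higher than 1.15 in the authors' deposited table. The order of genes by this measure was not tested against replicate error, and each table divided by its own spread put 51 genes above 3, where AURKB was highest at 7.26 and MEN1 had 5.18.

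Below that limit the highest scaled differences were 2.83 for ARID4B, a subunit of SIN3 corepressor complexes, 2.74 for ITGAV, the integrin alpha-V chain, 2.73 for METTL14, a subunit of the RNA N6-adenosine methyltransferase, 2.69 for TBL1X, a corepressor subunit, 2.54 for EHMT1, 2.5 for FCGR3A, an Fc receptor, 2.46 for TFPI and 2.45 for MMP11, a matrix metalloproteinase. ITGAV went from -2.67 in vitro to 0.53, and METTL14 from -0.57 to 2.61, in the authors' deposited table. Among the lowest were -2.22 for PAXIP1, -2.13 for ITGB1, the integrin beta-1 chain, -1.95 for the transcription factor STAT3, -1.84 for ADORA2B and -1.80 for ADORA1, both adenosine receptors, -1.83 for PSMB8, -1.82 for CACNA1C and -1.74 for KCNQ1, both ion channels, and -1.74 for RC3H2. Of the last group, ITGB1 had 0.12 in vitro and -3.51 in xenografts, and STAT3 -0.27 and -3.66, in the authors' deposited table. No gene named in this paragraph passed the FDR threshold in xenografts in either direction. For CACNA1C, at -3.10 in xenografts, the authors' one-sided MAGeCK p was 0.17 for depletion and 0.038 for enrichment.

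For lists, the difference between the arms itself passed for 0 of 29 (2 at an unadjusted permutation p below 0.05). The lowest adjusted permutation p was 0.21, for the H3K9 and H4K20 methylation list, whose median difference was 0.82 against -0.66 for random lists, and adjusted p ranged up to 0.87 for the others. The cell cycle list had a median difference of -1.72 (adjusted permutation p = 0.50) and the cholesterol and isoprenoid synthesis list 0.70 (0.50). The menin, KMT2A and COMPASS list had -0.24 (adjusted permutation p = 0.68).

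**Figure D2:**
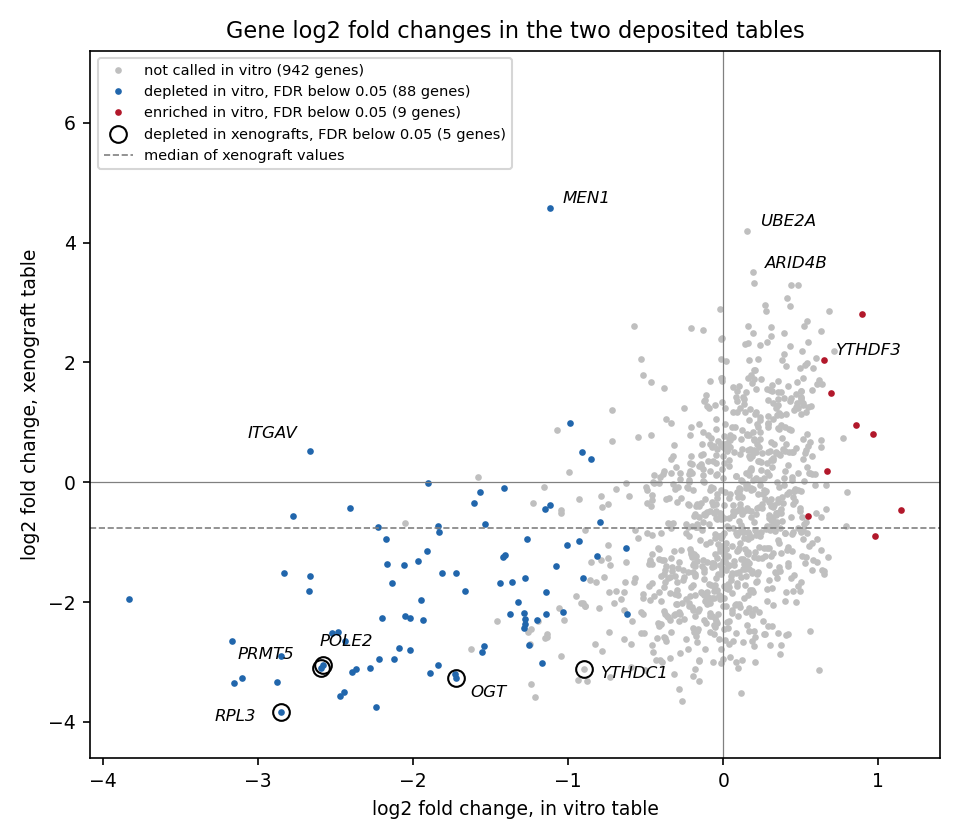
Log2 fold change of each of 1039 genes in the in vitro table (x axis) and the xenograft table (y axis) of the authors. Each point is a gene, coloured by its in vitro call, open circles mark the 5 genes depleted in xenografts, and the dashed line is the xenograft median of -0.77: MEN1 lies at -1.12 and 4.58, apart from the other genes depleted in vitro.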

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

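Of the tests in this part, the match of the shared value to guide length, its test against selection, the guide length and Y-linked tests of the control guides and the GC adjustment of the X- and Y-linked differences were chosen after the results were seen.

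Control guides were not part of the comparisons above and stood out in vitro. Relative to AAVS guides, named for the AAVS1 locus, the median log2 fold change was 0.97 higher for CTRL guides, 0.96 higher for LacZ guides and 0.97 higher for luciferase guides (100, 59 and 23 single-guide entries against 100, permutation p = 5e-05 each, the smallest that 20000 permutations can give, adjusted p = 5e-05). Guide length is argued against, because all these guides have 20 bases and the pooled difference was 0.97 (95% bootstrap interval 0.85 to 1.20). GC content is argued against as well, since the mean difference of 1.08 became 1.14 after adjustment (interval 0.96 to 1.33). A cost of cutting the genome is a candidate explanation that stays open. Among genes not called depleted, 45 X-linked genes had a median 0.19 above 900 autosomal genes (permutation p = 0.0032), or 0.17 after adjustment for guide GC content (permutation p = 0.0039), and 5 Y-linked genes lay 0.76 above (permutation p = 0.0011), or 0.72 (permutation p = 0.0015). Single autosomes differed as well: chromosomes 13, 18, 4 and 6 had medians of 0.44, 0.37, 0.31 and 0.23, against 0.23 for X and 0.80 for Y. The X-linked value thus lay within the spread of autosomes and cannot decide the question. The Y-linked value lay above every autosome but rests on 5 genes of a single chromosome. These permutations shuffled single genes, so their p-values do not measure the spread between chromosomes. In xenografts the GC-adjusted differences were 0.23 for X (permutation p = 0.34) and 1.02 for Y (permutation p = 0.20). The copy number of these chromosomes in the cells was not measured here, and no biological explanation from the design's groups was tested.

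The single value that 293 entries share in the xenograft table was weighed as a second pattern. It is held by 100% of entries made of 20-base guides and 0% of genes made of 19-base guides, so guides of 20 bases left without usable reads in that comparison are a candidate explanation. Loss of these guides by selection in the tumours is argued against by the pattern itself, not by an independent test. These 293 entries hold 1 value in the xenograft table, which defines the pattern, and 291 different values in vitro. Only the in vitro count could have come out otherwise. Which processing step set the value stays open, and with it the xenograft level of guides without a genomic target, so no zero point from controls exists for that table.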

How the results depend on the processing

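No paired analysis was possible because the tables hold 1 value per gene and comparison and no value per replicate, and leaving out replicates or re-splitting samples was not possible for the same reason. Alternatives with 20-base guide genes kept, control entries counted, adjustment over 19-base genes or GC adjustment were chosen after the data were seen. The 97 genes depleted in vitro ranged from 76 to 136, and the cross-arm correlation from 0.37 to 0.49, including 0.41 after GC adjustment.

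Thresholds set several counts by construction. At FDR thresholds of 0.01, 0.1 and 0.25, genes enriched in vitro numbered 4, 23 and 80 (main 9) and genes depleted in xenografts 0, 9 and 19 (main 5), while at 0.1 and 0.25 xenograft enrichment gave 1 and 13 (main 0). Joint adjustment of both directions gave 23 genes enriched in vitro and 0 depleted in xenografts, because p-values of the other direction enter the ranking. The overlap of enriched genes, untestable in the main setting with 0 genes called in xenografts, was 6 at an FDR threshold of 0.25 (Fisher exact p = 0.00019) and 7 for the 50 best-ranked genes (0.0079). At 2 scaled deviations 2 genes were lower and 26 higher in xenografts, at 4 deviations 1 was higher (MEN1), and scaling on the neurotransmitter list gave 5. Dividing each table by its own spread gave 51 higher genes, with AURKB highest at 7.26 and MEN1 at 5.18; this division enlarges in vitro depletion more than xenograft values. On that scale MEN1 itself stood at -2.70 in vitro and 2.97 in xenografts. The mean in place of the median made 1 list higher in vitro (neurotransmitter receptors and ion channels, adjusted permutation p = 0.0059), and ranking by p, chromosome centring and GC adjustment each left 0 lists higher in xenografts; the cause was not tested. Among single lists 7 alternative values lost the call, 1 gained it and 47 did neither. Depth is unknown, so its limit on any call cannot be given.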

Other observations

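Of the tests in this part, the number of MEN1 guides and the relation to GC content were chosen after the results were seen, as were the RNA methylation genes named.

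Genes of the N6-methyladenosine pathway of RNA were not a fixed list. In the authors' deposited table METTL3, the catalytic writer subunit, had -1.54 in vitro (FDR 0.00011) and -0.70 in xenografts, METTL14, its partner, had -0.57 and 2.61, and the adaptor WTAP -0.05 and -0.36. Among readers the authors' deposited table gave -0.90 and -3.12 for YTHDC1, 0.65 and 2.05 for YTHDF3, 0.02 and -1.02 for YTHDF1, -0.46 and -0.21 for YTHDF2, and 0.28 and 1.55 for YTHDC2, in vitro and in xenografts. The erasers FTO and ALKBH5 had 0.29 and 0.10 in vitro and -0.54 and 1.60 in xenografts in the authors' deposited table. Of these 10 genes, METTL3 (depleted) and YTHDF3 (enriched) passed in vitro and YTHDC1 (depleted) in xenografts.

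Low in vitro and first by enrichment rank in xenografts, MEN1 raised the question of a few outgrowing guides. Support for enrichment was not confined to 1 or 2 guides, since 7 of its 10 guides supported it in the authors' deposited table. The median was 4 for 956 other genes with 10 guides, 71 of which had 7 or more. The test could hardly decide on an outgrowth of 1 or 2 guides. It asked whether the count less 2 exceeded the 95th percentile of those genes, which was 7. Only 10 of 10 guides would have argued against it. Whether 1 or 2 guides set the size of the gene value stays open, because the rule that combined guides is not given. Enrichment shared with the menin partners KMT2A and PSIP1 could be read on KMT2A alone, because the other has no entry, and its xenograft value lay at the 86.5th percentile of random genes, between the bounds set beforehand, so this stays open too. How many tumours carried the MEN1 change is not visible in these tables, and drift in small tumour populations was not tested. A different role of MEN1 in the animal than in culture remains untested.

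Gene values fell with the GC content of their guides in both arms. Over 951 genes of 19-base guides not depleted in vitro, Spearman rho was -0.24 in vitro and -0.26 in xenografts (permutation p = 5e-05 each, the smallest that 20000 permutations can give). The fifth of genes with the lowest GC content (193 genes, median 44.2%) had medians of 0.23 and -0.05, and the fifth with the highest (187 genes, median 63.7%) had -0.013 and -1.24, in vitro and in xenografts.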
